A study of Mus musculus with 24 samples.

How the data were processed

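RNA from the mediobasal hypothalamus of mice was measured on 24 Affymetrix arrays, 3 for each of 2 conditions at each of 4 times of day. Total RNA was isolated with Trizol and labelled with biotin using the GeneChip WT Terminal Labeling Kit, per the labels. The submitters' processing notes name Affymetrix Expression Console, and its version and summarization method are not given in the sources used here. The values deposited by the authors are log2 probe-set signals, 35556 probe sets in each array, normalized across arrays by the authors. The condition of each array was taken from its description, and the time and replicate number from its title, with the numbers 1, 7, 13 and 19 read as zeitgeber time in hours.

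Some deposited cells had lost the place of their decimal point. A value was moved by factors of 10 back to the range of the log2 scale where its stored form allowed this, and where more than 1 place was possible the place nearest to the other arrays was taken. This restored 2792 of 853344 cells (0.327%), 655 of them in 606 probe sets with 1 gene symbol. A further 78 cells that had lost digits were set to missing, and 9 cells were missing as deposited. The median absolute deviation of the restored cells from the other arrays went from 7.20 before to 0.145 after, against 0.156 for the other cells. In a self-test, restored values of probe sets without missing cells were shifted again in the ways the rules assume. The step then restored 622 of 622 shifted cells and changed 0 unshifted ones. This checks the code and cannot show that the restored values are right.

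Gene symbols came from the annotation of the array, and 21789 probe sets had exactly 1 symbol, 1621 had several and 12146 had none. Of the first, 21698 were matched by Entrez number to a table of mouse genes of assembly GRCm38.p6, and 0 symbols needed an update. Probe sets with several symbols or none were left out, the probe set with the highest mean was kept for each gene, and probe sets under the 40th percentile of the means (5.86 log2 units) were removed. This left 11871 genes.

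Expression was modelled with limma 3.58.1 in R 4.3.3, with 8 group means fitted to all 24 arrays and empirical Bayes moderation with a trend on the mean level. Differences are TSR minus CON, on the log2 scale, with the moderated standard error, and these tests were 2-sided. The average effect was the mean of the 4 differences within times. A 24-h rhythm was tested by an F test on 2 contrasts, ZT1 against ZT13 and ZT7 against ZT19, in each condition, in their mean and in their difference. Amplitude is the distance from mean to peak of the fitted cosine. With steps of 6 h, some rhythms with shorter periods cannot be separated from it. P-values were adjusted by the method of Benjamini and Hochberg over genes within each test, and an adjusted p under 0.05 passed. Amplitudes and peaks were compared by swapping condition labels within times in 100 draws.

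Before the data were examined, 34 gene lists were written for cell types, brain regions and pathways, along with the comparisons and the other settings to be tried. Of the lists, 30 had at least 5 tested members. They were tested with camera at a preset correlation of 0.01, over 150 combinations of list and contrast, and again with the correlation estimated from the data. Rhythmic members were compared with other genes by a 1-sided Fisher's exact test for a larger share in the list. The other 4 lists were not tested, and further lists were written after the results were seen.

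Most genes named in the report were taken from sets given by a fixed rule. For the average effect it takes the 12 largest increases and the 12 largest decreases among genes past the threshold with the same sign at all 4 times. At each time it takes the 4 largest in each direction in which all 3 TSR values lie on one side of all 3 CON values. For rhythms it takes the clock genes and the 8 largest amplitudes in each condition, and for the difference in rhythm the 12 smallest p-values. It adds up to 4 members of each list and a set of 19 genes of sleep, feeding and the clock. The text names only some members of these sets, and no rule was fixed for which of them are named. Abcb1a, Pecam1, Syt10, Dnaja1, Hsph1, Mobp, Mag and Mbp fall outside the rule and were chosen after their values were seen, as were the contrasts at which genes named by 1 part of the rule are also given.

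Other settings covered the filter, the choice of probe sets, normalization, moderation, array weights, thresholds, a block for replicate number, other rhythm models, fits to part of the arrays and leaving out 1 array at a time. Alternatives with the 4 arrays of narrow distribution left out or fitted as a block, and with the decimals as deposited or the shifted cells blank, were added after the data were seen. An array was called narrow when its interquartile range was under 2.5 log2 units. Simulations changed 100 genes at each of 2 sizes, with independent noise of each gene's spread, the same on every array. Tested on simulated changes in 100 of 11871 genes, the model recovered 49 average effects of 0.5 log2 with 24 arrays and 96 with 20, and 86 and 100 of 1 log2. For rhythms in controls with an amplitude of 0.5 it recovered 35 and 96, and with an amplitude of 1 it recovered 85 and 100. Such noise leaves out what the 4 narrow arrays share, so these recovered shares need not hold for the real data. Preparation and figures used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.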

Results

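Gene expression was measured in the mediobasal hypothalamus, the base of the hypothalamus that holds the arcuate nucleus, a centre of appetite and energy balance. Tissue came from mice in 2 conditions at 4 times of day, read as zeitgeber time (ZT, hours after lights on) 1, 7, 13 and 19. Mice under timed sleep restriction (TSR) were kept awake by gentle handling from ZT0 to ZT6 on 5 days in a row. They then slept freely for 2 days and were restricted for a further 5 days, while control mice (CON) stayed undisturbed. Each of the 8 groups held 3 arrays, 24 in all, and their number limits the precision. The day on which tissue was taken is not given in the sources used here. The question was how sleep restriction placed in the usual rest phase affects transcript levels and their daily rhythms in this region. The description of the series gives 3 mice at each time point in each condition, the number of arrays in a group. P-values measure the spread between these samples, part of which may be technical.

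In 4 of the 24 arrays the values were spread over a narrower range than in the others. The interquartile range was 2.18 log2 units for TSR ZT1 replicate 3, 2.25 for TSR ZT13 replicate 2, and 2.12 and 2.14 for CON ZT19 replicates 2 and 3, against 2.96 to 3.29 in the other 20 arrays. Their median Spearman correlation with the other arrays, taken across probe sets, was 0.836 to 0.882, against 0.976 to 0.986. The median residual standard deviation (SD) of a gene was 0.36 log2 units in the fit of 24 arrays and 0.11 without these 4. Each count is therefore also given for the 20 arrays, an alternative chosen after the data were seen. Control mice at ZT19 then have 1 array, which is assumed to vary like the other groups. The median over all genes differed between conditions in the groups with narrow arrays. The median difference over all 11871 genes, TSR minus CON, was -0.22 at ZT1, -0.18 at ZT13 and 0.60 at ZT19, and became -0.08, -0.05 and 0.18 when the arrays were quantile normalized again. Without the narrow arrays these medians were 0.04, -0.00 and 0.08.

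**Figure D1:**
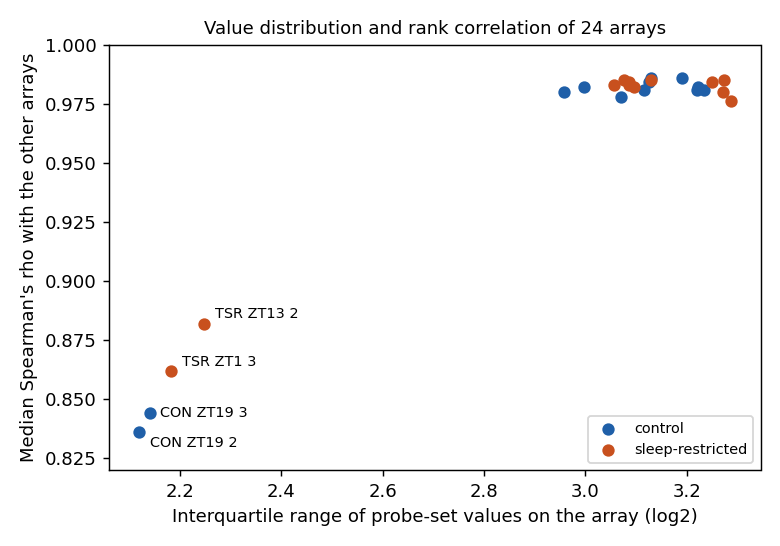
Each point is 1 of the 24 arrays, with the interquartile range of its probe-set values (log2) on the horizontal axis and its median Spearman correlation with the other arrays on the vertical axis. The 4 labelled arrays lie between 2.12 and 2.25 log2 units, apart from the other 20 at 2.96 to 3.29.

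Averaged over the 4 times, Lhx8 was higher in TSR by 0.81 ± 0.10 log2 units (SE, 12 arrays in each condition). Its limma adjusted p was 3.59e-04. Lhx8 is a transcription factor of forebrain cholinergic neurons, and tissue of a neighbouring region may account for its difference, as set out below. The dopamine receptor gene Drd3 rose by 0.64 ± 0.10, the guidance cue Sema3e by 0.65 ± 0.10, the sodium channel gene Scn1a by 0.67 ± 0.14, and Tnfaip6, which acts on the extracellular matrix, by 0.77 ± 0.16. The largest decrease was in n-R5s136, a 5S ribosomal RNA gene, which fell by 1.56 ± 0.13 (adjusted p = 8.36e-07). Rny3, a small noncoding RNA that binds Ro protein, fell by 0.77 ± 0.18, the imprinted hypothalamic gene Magel2 by 0.53 ± 0.10, and the interneuron transcription factor Dlx2 by 0.52 ± 0.11. The clock gene Per2 fell by 0.37 ± 0.06 (adjusted p = 0.00382). Each gene named here apart from Per2 differed in the same direction at all 4 times.

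Of 11871 genes, 286 passed in the average effect of sleep restriction, 87 higher and 199 lower in TSR, and 1920 had an unadjusted p under 0.05. After quantile normalization 1590 passed, and the share of higher genes moved from 30.4% to 45.2%. Without the 4 narrow arrays 6715 genes passed, 3995 higher and 2720 lower, including all 286. Leaving out 1 array moved the count by over 1.5 times for 18 of the 24, from 155 without TSR ZT19 replicate 1 to 1291 without TSR ZT13 replicate 2.

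The gene lists fixed beforehand gave 5 calls in the average effect. Of 21 core clock genes measured, 1 fell over all genes tested and 1 when adjusted over the list alone (camera adjusted p = 0.0437, and adjusted p = 0.996 with an estimated correlation). Suprachiasmatic nucleus markers, which name the master clock next to this region, were lower, with 2 of 12 fallen, 5 adjusted over the list alone (adjusted p = 0.0109, and 0.996 with an estimated correlation). Paraventricular and supraoptic markers were lower, with 2 of 8 fallen, Magel2 among them, and 3 adjusted over the list alone (adjusted p = 0.0168, and 0.996 with an estimated correlation). Thalamus and cortex markers were higher, among them Foxp2, which rose by 0.70 ± 0.12, and the glutamate transporter gene Slc17a7, which rose by 0.67 ± 0.11, 2 of 10 members, 4 adjusted over the list alone (adjusted p = 0.0035, and 0.565 with an estimated correlation). Endothelial and mural markers were higher, with 1 of 14 risen, the efflux pump gene Abcb1a at 0.42 ± 0.09, and 7 adjusted over the list alone (adjusted p = 0.0045, and 0.931 with an estimated correlation). Over all 150 tests of 30 lists at 5 contrasts, 25 passed with the preset correlation and 0 with an estimated one, where limma's camera gave 11 at an unadjusted p under 0.05. In the 20 arrays 35 and 4 passed.

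Several genes of interest for sleep and feeding did not pass in the average effect with 24 arrays. Npy, which encodes an appetite-raising peptide, differed by -0.23 ± 0.10 (adjusted p = 0.243), and the satiety gene Cartpt by -0.29 ± 0.09 (adjusted p = 0.101). The glucocorticoid-responsive genes Sgk1 and Fkbp5 differed by 0.60 ± 0.17 (adjusted p = 0.0582) and 0.05 ± 0.12 (adjusted p = 0.886). With the 20 arrays Npy (-0.26 ± 0.09, adjusted p = 0.0234), Cartpt (-0.26 ± 0.07, adjusted p = 0.00316) and Sgk1 (0.74 ± 0.06, adjusted p = 4.32e-09) passed, and Fkbp5 did not (adjusted p = 0.0553). Of 20 appetite and energy balance genes 8 rose and 10 fell there, and the list itself was not called (camera adjusted p = 0.819). With 24 arrays 1 of the 20 fell, 6 adjusted over the list alone. Agrp, Pomc, Fos and Dio2 lay below the expression filter and were not tested.

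ZT1 lies within the hours of daily restriction by clock time. At ZT1, Serpina1c, a protease inhibitor of the plasma, rose in TSR by 3.70 ± 0.62 log2 units (SE, n = 3 in each group; adjusted p = 0.0281), albumin (Alb) by 3.31 ± 0.47 (adjusted p = 0.00446), the apolipoprotein gene Apoa1 by 1.67 ± 0.30 and transthyretin (Ttr), which carries thyroid hormone, by 1.28 ± 0.23. Alb went from 5.74 ± 0.19 in controls to 9.04 ± 1.52 in TSR (mean ± SD). n-R5s136 fell by 2.14 ± 0.25, and Fabp7, a fatty acid binding protein of astrocytes, fell by 1.26 ± 0.23 (adjusted p = 0.0376). The control means of Serpina1c (4.12), Alb and Ttr lay under the filter threshold of 5.86. Signal was not shown to stand above background there, so the sizes of these 3 differences are uncertain. In each of the 6 genes all 3 TSR values lay on one side of all 3 control values.

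Those 6 genes, 4 higher and 2 lower, were all that passed for the effect of sleep restriction at ZT1, where 487 had an unadjusted p under 0.05. Fitted to only the 6 arrays of ZT1, limma called 0 genes, with 144 at an unadjusted p under 0.05. After quantile normalization 19 passed, with 31.6% higher against 66.7%. The count moved by over 1.5 times on leaving out 1 array for 18 of the 24, from 1 without TSR ZT1 replicate 2 to 9 without TSR ZT13 replicate 2. In 15.1% of genes the groups did not overlap, against 10% by chance, and an exact test of 3 against 3 cannot give a p under 0.1. Without the 4 narrow arrays, 1200 genes passed, 830 higher and 370 lower (69.2% higher, and 51.1% after quantile normalization). The myelin genes stood out in that fit. Of 18 oligodendrocyte and myelin markers 16 rose, Mobp by 0.90 ± 0.10, Mag by 0.77 ± 0.08 and Mbp by 0.42 ± 0.07 (camera adjusted p = 2.51e-16, and adjusted p = 0.0295 with an estimated correlation), although with all 24 arrays none of them passed. Of 11 arcuate and ventromedial markers 4 fell in the 20 arrays, among them the neurokinin gene Tac2 by 0.65 ± 0.14 (adjusted p = 5.79e-04, and 0.0358 with an estimated correlation). With all 24 arrays the meninges (adjusted p = 0.0182, and 0.931 with an estimated correlation) and interferon response lists (0.00537, and 0.168) were called higher, and the neuron (0.0318, and 0.996) and mitochondrial respiratory chain lists (0.00593, and 0.996) lower. No member of these 4 lists passed by itself in limma, over all genes or adjusted over the list alone. None of the 4 lists was called in the 20 arrays (adjusted p = 0.738, 0.318, 0.365 and 0.329), and the direction of the meninges list turned.

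ZT7 follows the hours of daily restriction by clock time. At ZT7, Slc5a7, the choline transporter of cholinergic nerve endings, rose in TSR by 3.16 ± 0.41 log2 units, from 5.73 ± 0.13 to 8.89 ± 0.16 (mean ± SD, n = 3; adjusted p = 0.00111). This control mean lay under the filter threshold of 5.86, where signal was not shown to stand above background, so the size of the difference is uncertain. The vesicular acetylcholine transporter gene Slc18a3 rose by 2.16 ± 0.32 and the muscarinic receptor gene Chrm2 by 1.67 ± 0.33. Meis2, a forebrain transcription factor, rose by 2.09 ± 0.41. Tissue of a neighbouring region may account for these cholinergic and forebrain genes, as set out below. Egr1, an immediate early gene of neuronal activity, rose by 0.80 ± 0.14, from 6.23 ± 0.16 to 7.04 ± 0.03. Vipr2, the receptor through which vasoactive intestinal peptide couples clock neurons, fell by 1.23 ± 0.20, Per2 by 0.57 ± 0.12, n-R5s136 by 1.31 ± 0.25, Stoml3 by 1.22 ± 0.18 and Spata18 by 1.21 ± 0.24, the TSR means of Stoml3 and Spata18 lying under the same threshold. The chaperone gene Hspa5, often used as a marker of sleep loss, differed by 0.57 ± 0.36 with 24 arrays (adjusted p = 1) and rose by 0.57 ± 0.06 with 20 (adjusted p = 1.58e-06).

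**Figure D2:**
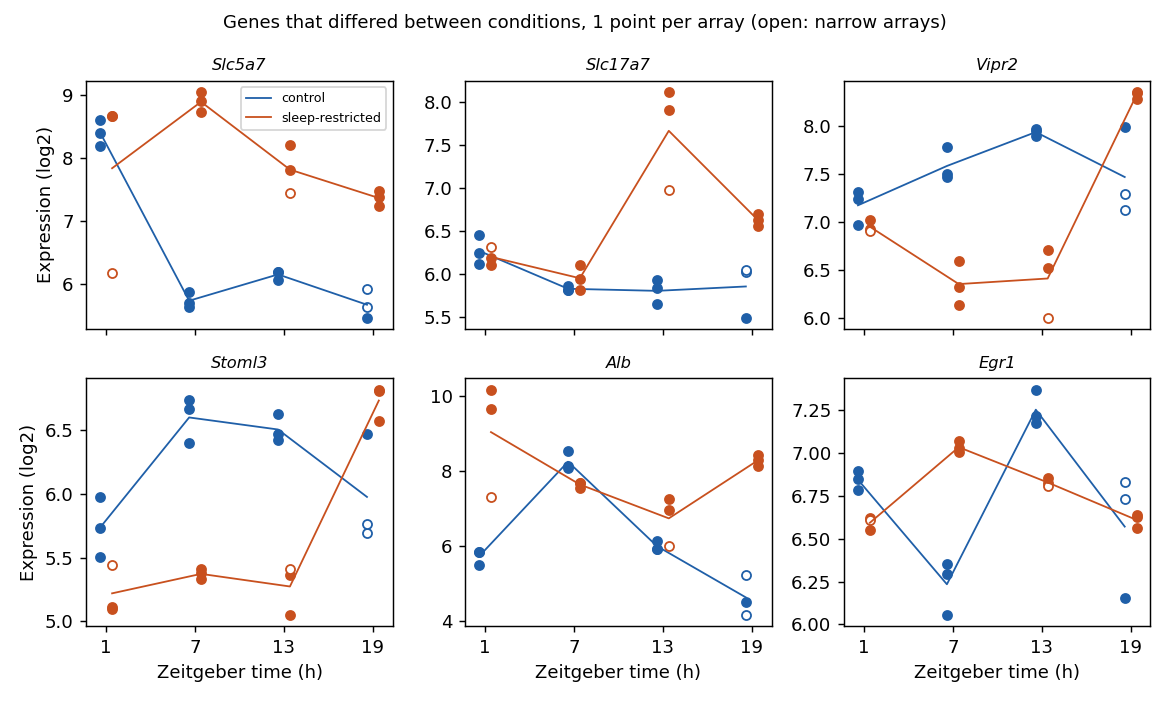
Expression (log2) of 6 genes against zeitgeber time (h), with 1 point per array, lines through the group means of 3 arrays and open points for the 4 narrow arrays. Slc5a7 at ZT7 averaged 8.89 in sleep-restricted mice and 5.73 in controls, and Alb at ZT19 averaged 8.29 and 4.64.

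At ZT7, where neither group holds a narrow array, 51 genes passed, 26 higher and 25 lower, and 649 had an unadjusted p under 0.05. In 36.2% of genes the groups did not overlap, against 10% by chance. With the spread estimated from the 20 typical arrays 3191 passed, 1541 higher and 1650 lower, including all 51. Leaving out 1 array moved the count by over 1.5 times for 9 of the 24, from 2 without CON ZT7 replicate 1 to 114 without TSR ZT1 replicate 3.

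At ZT7, 4 lists were called lower. Suprachiasmatic markers were lower, with 0 of 12 passing over all genes in the 24-array limma fit, 4 adjusted over the list alone and 10 in the 20 arrays (adjusted p = 3.42e-08, and 0.546 with an estimated correlation). In the 20 arrays the regulator of G protein signalling Rgs16 fell by 1.07 ± 0.07 and Syt10 by 0.73 ± 0.06, and this list passed there with an estimated correlation as well (adjusted p = 0.0295). Paraventricular and supraoptic markers were lower too (adjusted p = 5.59e-05, and 0.546 with an estimated correlation), and 7 of 8 fell in the 20 arrays, the releasing hormone gene Trh by 1.54 ± 0.09 and the vasopressin gene Avp by 0.40 ± 0.06 (adjusted p = 0.0295 with an estimated correlation). Core clock genes were lower, 1 of 21 over all genes, 2 adjusted over the list alone and 13 in the 20 arrays (adjusted p = 2.15e-04, and 0.996 with an estimated correlation), as were tanycyte and ependymal markers, with 0 of 11, 3 adjusted over the list alone and 7 in the 20 arrays (adjusted p = 9.77e-04, and 0.08 with an estimated correlation).

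Other lists were called higher at ZT7. Endothelial and mural markers were higher, with 2 of 14 risen, the adhesion gene Pecam1 by 0.68 ± 0.15 and Abcb1a by 0.82 ± 0.18, 6 adjusted over the list alone (adjusted p = 3.42e-08, and 0.46 with an estimated correlation). Heat shock genes were higher, with 0 of 17 passing in the 24 arrays and 12 in the 20 (adjusted p = 0.00291, and 0.996 with an estimated correlation), Dnaja1 rising by 0.49 ± 0.10 and Hsph1 by 0.37 ± 0.07 in the latter. Thalamus and cortex markers were higher, with Foxp2 at 1.28 ± 0.24 (1 of 10, 2 adjusted over the list alone, adjusted p = 0.002, and 0.546 with an estimated correlation). Neuron markers (adjusted p = 0.0331), sleep and wake regulators (adjusted p = 0.0331) and oligodendrocyte precursor markers (adjusted p = 0.028) were also higher, each with an adjusted p = 0.996 with an estimated correlation. Adjusted over the list alone, 1 of 18, 3 of 14 and 1 of 14 of these passed. The precursor list was not called in the 20 arrays (adjusted p = 0.0756).

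At ZT13, in the early dark phase, Slc17a7, a vesicular glutamate transporter of cortical neurons, rose by 1.86 ± 0.21 log2 units in TSR (SE, n = 3; adjusted p = 3.01e-04) and by 2.21 ± 0.12 in the 20 arrays. The neuronal transcription factor Mef2c rose by 1.02 ± 0.17. Vipr2, the receptor named above, fell by 1.53 ± 0.20, and Prokr2, the receptor of a suprachiasmatic output peptide, fell by 1.42 ± 0.21. Per2 fell by 0.90 ± 0.12, from 7.97 ± 0.13 to 7.08 ± 0.12 (mean ± SD; adjusted p = 0.00197), and Rasd1, a small G protein gene that acts in light signalling to the clock, fell by 1.20 ± 0.17. The vault RNA Vaultrc5 fell by 2.53 ± 0.39 and n-R5s136 by 1.46 ± 0.25. The control mean of Slc17a7 and the TSR mean of Vaultrc5 lay under the filter threshold of 5.86, so the sizes of their differences are uncertain.

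For the effect of sleep restriction at ZT13, 49 genes passed, 9 higher and 40 lower, and 1623 had an unadjusted p under 0.05. A limma fit to only the 6 arrays of that time called 0, with 1031 at an unadjusted p under 0.05. TSR holds 1 narrow array here, and without the 4 narrow arrays 5483 passed, 2871 higher and 2612 lower. After quantile normalization of the 24 arrays 628 passed, with 32.0% higher against 18.4%. The count moved by over 1.5 times on leaving out 1 array for 20 of the 24, from 7 without CON ZT13 replicate 3 to 415 without TSR ZT1 replicate 3. In 27.4% of genes the groups did not overlap, against 10% by chance. Core clock genes were lower, 1 of 21 over all genes, 7 adjusted over the list alone and 13 in the 20 arrays (adjusted p = 4.29e-05, and 0.996 with an estimated correlation). Suprachiasmatic markers were lower, with 0 of 12 over all genes in limma and 4 adjusted over the list alone, and so were paraventricular and supraoptic markers, with Magel2 falling by 1.04 ± 0.19 and 4 of 8 adjusted over the list alone. Both lists had an adjusted p = 0.0168, and 0.996 with an estimated correlation. Thalamus and cortex markers were higher, with Slc17a7 the 1 of 10 that rose (adjusted p = 0.00665, and 0.648 with an estimated correlation), as were meninges markers, of which 0 of 7 passed in limma (adjusted p = 0.0166, and 0.931 with an estimated correlation). The meninges call was lost in the 20 arrays, where its direction turned (adjusted p = 0.996). The paraventricular and supraoptic list (adjusted p = 0.069) and the thalamus and cortex list (adjusted p = 0.0884) kept their direction there without passing.

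At ZT19, in the dark phase, Alb rose in TSR by 3.65 ± 0.47 log2 units, from 4.64 ± 0.55 to 8.29 ± 0.14 (mean ± SD, n = 3; adjusted p = 0.00206), and Serpina1c rose by 3.01 ± 0.62. Both control means lay under the filter threshold of 5.86, so the sizes of these differences are uncertain. Both differed by a similar amount in the 20 arrays, Alb by 3.78 ± 0.19 and Serpina1c by 3.47 ± 0.46. Ano3, a membrane protein gene, rose by 2.62, but by 1.15 ± 0.24 in the 20 arrays. The largest decreases were in Sp140, at -3.87 ± 1.26, and Tctex1d2, at -3.26, against -1.34 ± 0.26 and -0.57 in the 20 arrays. The control mean of Ano3 and the TSR means of Sp140 and Tctex1d2 lay under the same threshold. Vipr2, lower at ZT7 and ZT13, rose here by 0.86 ± 0.20, but did not pass in the 20 arrays (0.34 ± 0.15, adjusted p = 0.111).

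The effect of sleep restriction at ZT19 was called in 6571 genes, 5267 higher and 1304 lower, with 7779 at an unadjusted p under 0.05. A fit to only the 6 arrays of that time called 4. It rested on a control group with 2 narrow arrays of 3. With the 20 arrays 2954 passed, 2109 higher and 845 lower. Of these, 2203 were shared with the 24-array calls, 2191 in the same direction. Quantile normalization moved the share of higher genes from 80.2% to 59.5% in the 24 arrays and from 71.4% to 51.7% in the 20. Leaving out 1 array moved the count by over 1.5 times for 5 of the 24, from 1 without TSR ZT19 replicate 2 to 9275 without CON ZT19 replicate 1, the only typical array of its group. The groups did not overlap in 56.7% of genes, against 10% by chance. Meninges markers were lower, with 1 of 7 risen and 3 fallen, 4 adjusted over the list alone (adjusted p = 0.00967, and 0.83 with an estimated correlation). This call was lost in the 20 arrays (adjusted p = 0.775), with 1 of 7 risen.

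In control mice 2 core clock genes passed the test for a 24-h rhythm. Dbp, an output of the clock, had an amplitude of 0.88 ± 0.12 log2 units (SE, 12 arrays) and a peak at ZT 9.5 (adjusted p = 0.00705), and Per2 an amplitude of 0.54 ± 0.06 and a peak at ZT 11.4 (adjusted p = 0.00155). Rasd1 peaked at ZT 12.8 with an amplitude of 0.72 ± 0.09 and Ppp1r1b, a dopamine signalling gene, at ZT 13.8. Fabp7 peaked at ZT 3.4, the metal-binding gene Mt2 at ZT 6.5, Rgs16 at ZT 6.6 and Alb at ZT 7.3, with an amplitude of 1.81 ± 0.23. Per1, with an amplitude of 0.62 ± 0.12, missed the threshold (adjusted p = 0.0753), as did Nr1d1 (0.80 ± 0.19, adjusted p = 0.158), but in the 20 arrays both passed, with amplitudes of 0.53 ± 0.04 and 0.47 ± 0.04.

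In controls 13 genes were rhythmic, with 3752 at an unadjusted p under 0.05, and 2559 in the 20 arrays, which include the 13. The count moved by over 1.5 times on leaving out 1 array for 20 of the 24, from 6 without CON ZT7 replicate 1 to 7794 without CON ZT19 replicate 1. Of the 21 core clock genes 2 were among the 13, a larger share than among other genes (Fisher's exact test, 1-sided, adjusted p = 0.00689). Adjusted over the list alone 15 of the 21 passed, which that test did not cover. In the same fit 15 of 18 oligodendrocyte and myelin markers passed over their own list, so such a count was not particular to the clock genes. In the 20 arrays 13 of 21 were rhythmic (Fisher's exact test, adjusted p = 4.41e-04), and 7 other lists passed as well, oligodendrocyte and myelin markers (15 of 18, adjusted p = 1.22e-06) and suprachiasmatic markers (10 of 12, adjusted p = 1.37e-04) with the smallest p-values. The others were the glucocorticoid response, other neuropeptides, immediate early genes, tanycyte and ependymal markers and thyroid hormone signalling. In that fit controls at ZT19 have 1 array. The mean of the myelin markers, set against the 20 typical arrays, was -0.520 log2 units in that array. It was -0.178 to 0.078 in the other typical control arrays, so the control myelin rhythm rests on 1 array. Fisher's exact test also treats the genes of a list as independent.

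In sleep-restricted mice 10 genes passed the test for a 24-h rhythm. Vipr2 had an amplitude of 1.02 ± 0.10 log2 units and a peak at ZT 20 (adjusted p = 1.39e-04), and Slc17a7 an amplitude of 0.81 ± 0.11 and a peak at ZT 14.7 (adjusted p = 0.00453). Hydin, which builds the axoneme of motile cilia, peaked in the dark phase, at ZT 19.4 with an amplitude of 0.53 ± 0.08. Spata18 did so at ZT 18.6 with 0.82 ± 0.12 and Stoml3 at ZT 18.8 with 0.68 ± 0.09. Rasd1 peaked at ZT 18.1, and Kcnmb1, a potassium channel subunit gene, at ZT 19. Of the core clock genes 0 of 21 passed in limma, over all genes, in TSR in the 24-array fit and 5 in the 20 (Fisher's exact test, adjusted p = 0.697 for the latter). Among the lists that passed for TSR in the 20-array fit were oligodendrocyte and myelin markers (15 of 18, adjusted p = 1.27e-06) and suprachiasmatic markers (10 of 12, adjusted p = 9.38e-05). In limma 277 genes had an unadjusted p under 0.05, and 2566 passed in the 20 arrays. Leaving out 1 array moved the count by over 1.5 times for 8 of the 24, from 3 without TSR ZT19 replicate 3 to 38 without TSR ZT1 replicate 3.

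A rhythm in the mean of both conditions was found in 6 genes, Fabp7, Ccdc162, Ppp1r1b, Rasd1, Vipr2 and Dusp4, a phosphatase gene of the MAP kinase pathway. Fabp7 peaked at ZT 3.4 in controls and ZT 5.8 in TSR, Dusp4 at ZT 4.1 and ZT 5.4, and Ppp1r1b at ZT 13.8 and ZT 10.9. Vipr2 peaked at ZT 12.4 and ZT 20, Ccdc162 at ZT 11.8 and ZT 17.9, and Rasd1 at ZT 12.8 and ZT 18.1. Amplitudes in controls and TSR were 0.9 and 0.2 log2 units for Fabp7, 0.44 and 0.25 for Dusp4, and 0.61 and 0.37 for Ppp1r1b. They were 0.39 and 1.02 for Vipr2, 0.37 and 0.5 for Ccdc162, and 0.72 and 0.67 for Rasd1. Where the amplitude is low, as for Fabp7 in TSR, the peak is uncertain. In the 20 arrays 848 genes passed, the 6 included, and with 24 arrays 581 had an unadjusted p under 0.05. The count moved by over 1.5 times on leaving out 1 array for 20 of the 24, from 2 without TSR ZT1 replicate 2 to 78 without TSR ZT1 replicate 3.

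The rhythm itself differed between conditions in 22 genes by limma's test of the difference, among them Vipr2 (adjusted p = 0.00194), Stoml3, Alb, Rasd1, Hydin, Slc17a7, Per2 and Prokr2 (12 arrays in each condition). Per2 had an amplitude of 0.54 ± 0.06 in controls and 0.04 ± 0.06 in TSR (adjusted p of the difference 0.0158). Alb peaked at ZT 7.3 in controls and at ZT 24 in TSR, and Rasd1 at ZT 12.8 and ZT 18.1. Of the core clock genes 1 of 21 differed, 4 adjusted over the list alone (Fisher's exact test, adjusted p = 0.574). Without the 4 narrow arrays 13 of 21 differed (adjusted p = 0.0178), and 5 other lists passed as well. These were suprachiasmatic markers (10 of 12, adjusted p = 0.00464), other neuropeptides (14 of 21, adjusted p = 0.00595), tanycyte and ependymal markers (8 of 11, adjusted p = 0.026), sleep and wake regulators (9 of 14, adjusted p = 0.0398) and paraventricular and supraoptic markers (6 of 8, adjusted p = 0.0479). In the 20 arrays the amplitude of Per1 was 0.53 ± 0.04 in controls and 0.10 ± 0.05 in TSR, that of Dbp 0.63 ± 0.04 and 0.23 ± 0.04, that of Nr1d1 0.47 ± 0.04 and 0.20 ± 0.03, and that of Ciart, a repressor of the clock, 0.56 ± 0.06 and 0.12 ± 0.06.

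**Figure D3:**
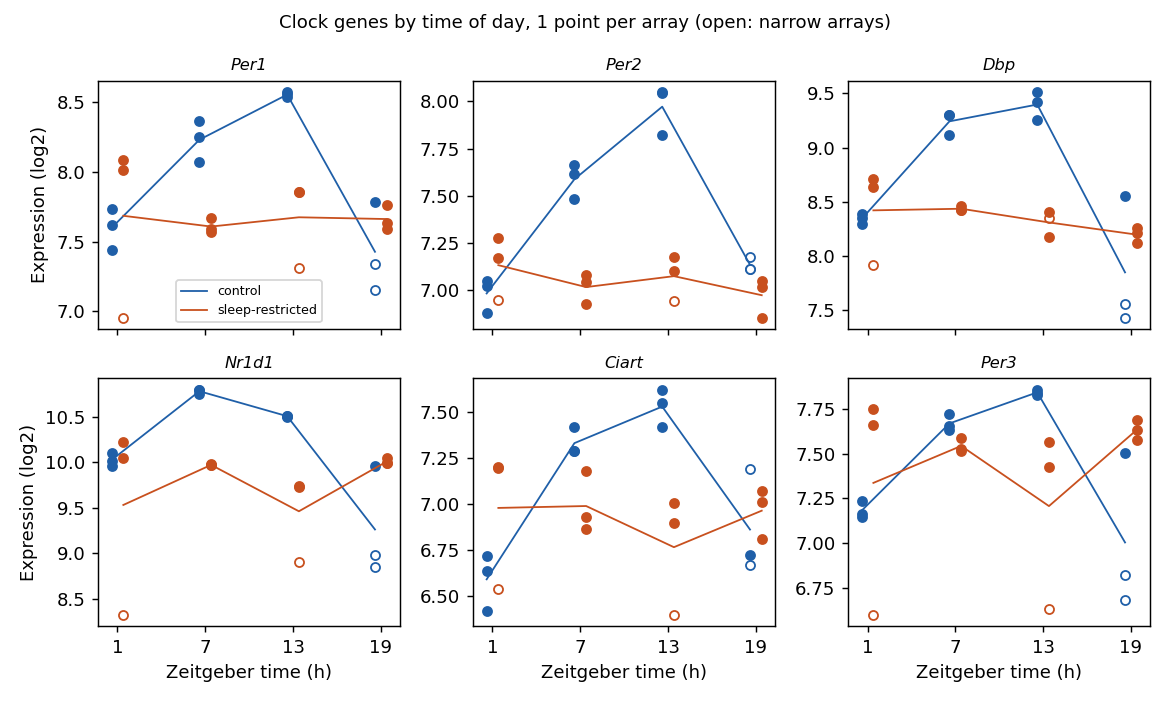
Expression (log2) of 6 clock genes against zeitgeber time (h), with 1 point per array, lines through the group means of 3 arrays and open points for the 4 narrow arrays. Per2 at ZT13 averaged 7.97 in controls and 7.08 in sleep-restricted mice.

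With 24 arrays 1382 genes had an unadjusted p under 0.05 for the difference in rhythm, and in the 20 arrays 3455 passed, including the 22. Leaving out 1 array moved the count by over 1.5 times for 8 of the 24, from 7 without CON ZT7 replicate 2 to 3440 without CON ZT19 replicate 1.

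Among the 6 genes rhythmic on average, Fabp7 to Dusp4, the median log2 ratio of amplitudes, TSR over CON, was -0.41 (permutation p = 1) and the mean peak shift 3.61 h later in TSR (permutation p = 0.5). Only 3 of 100 draws of permuted labels had any such gene, so these permutation p-values rest on few draws. The core clock genes behaved otherwise. Over the 21 genes of that list, Per1, Per2 and Dbp among them, the median log2 ratio was -2.57 in the 24 arrays and -1.25 in the 20, each with a permutation p of 0.0099, the smallest that 100 draws can give. Over all genes the median log2 ratio was -1.64 in the 24 arrays, a difference of -0.93 for the clock list (permutation p = 0.0297), and 0.01 in the 20, a difference of -1.26 (permutation p = 0.0099, the smallest possible). In the 20 arrays the amplitude was higher in TSR in 5 of 21. Per1, Dbp, Nr1d1 and Ciart, whose amplitudes are given above, are not among these 5. The mean peak shift of the list was -10.61 h in the 24 arrays (permutation p = 0.0198) and -10.78 h in the 20. This shift takes in genes with low TSR amplitudes, whose peaks are uncertain, and it was not computed without them. For the 848 genes rhythmic on average in the 20 arrays the ratio was 0.03 (permutation p = 0.919).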

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

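The test of the difference in rhythm was fixed earlier, and the tests of the 3 patterns and the splits were chosen after the results were seen.

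The difference between the rhythms of the 2 conditions, tested itself, brought out 12 genes. For Vipr2 the adjusted p was 0.00194, for Stoml3 0.00281, for Alb 0.00599, for Rasd1 0.0086, for Hydin 0.0115 and for Slc17a7 0.0118. For 1700013F07Rik, Spata18, Per2, Ccdc162, Prokr2 and Map3k15 it was 0.0158. These genes include a receptor of clock neurons, a core clock gene, a ciliary gene and a marker of cortical neurons, and they are the smallest p-values of 22 that passed.

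The first pattern is the narrow distribution of 4 arrays. The condition or time of the mice is argued against, since the other 5 arrays of their groups had an interquartile range of 2.998 log2 units or more, within the range of the 15 arrays of the other groups. A scale difference in the deposited values is argued against as well, since it would keep ranks, while the highest Spearman correlation of a narrow array with a typical array of its group was 0.724, under the lowest between typical arrays of different groups, 0.937 (across genes, which are not independent replicates). A measurement fault shared by the 4 arrays remains a candidate explanation: their deviations from their own groups went together, with a correlation across genes of at least 0.777 in 5 pairs, against a median of 0.006 and a highest of 0.531 in 154 pairs of typical arrays.

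The second pattern is that markers of neighbouring brain regions moved with group, such as cholinergic genes up and suprachiasmatic and paraventricular genes down at ZT7. If each array is 1 mouse, tissue blocks that differ from mouse to mouse are argued against. The spread of 46 region markers within groups was 1.086 times that of other genes, while between groups it was 1.852 times. These groups differ in time of day as well as in condition, so the value between groups can also hold daily rhythms of the markers. Tissue of a neighbouring region taken with a whole group may account for the pattern. At ZT7 the median of 13 tested striatal markers, without the 2 seen among the top genes, lay at percentile 100 of 10000 random lists. At ZT13 the same 13 genes lay at percentile 0.39 (1.54 without the narrow arrays) while cholinergic genes stayed at percentile 100. The cholinergic list was written after the ranked genes had been seen, and seen genes were not taken out of it. The 2 percentiles are therefore not alike, and they cannot settle whether 1 source held both sets. An effect of sleep restriction on these neurons stays open and was not tested.

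The third pattern is the smaller amplitude of clock genes after sleep restriction. The narrow control arrays at ZT19 are argued against as the whole cause, since without the 4 narrow arrays the median log2 ratio was -1.25, outside the central range of the label draws, -0.87 to 0.89. A smaller amplitude of genes in general is argued against as the whole cause, since the median ratio over all genes was 0.01 without the narrow arrays. With all 24 arrays it was -1.64, with the clock genes a further -0.93 from it (permutation p = 0.0297). This second comparison was not matched on expression level. The mean of the clock list was -1.156 and -1.131 in the narrow CON ZT19 replicates 2 and 3, against -0.106 in replicate 1. The value of -0.93 therefore cannot be separated from the effect of the narrow arrays. A lower share of suprachiasmatic tissue in the restricted groups at ZT7 and ZT13 cannot be told apart from a change within cells: without the narrow arrays 17 clock genes with a daytime or evening peak changed by a median of -0.43 at ZT13 and -0.34 at ZT7, and 10 suprachiasmatic markers by -0.41 and -0.50. An effect of sleep restriction on the clock stays open and was not tested further.

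Arrays were also split at random. For the average effect, 1 of 100 draws of condition labels, the real one, gave as many genes (286, highest other 3). So it was for the difference in rhythm (22, highest other 1). With time labels drawn again, the same held for the rhythm in controls (13, highest other 1), in sleep-restricted mice (10, highest other 1) and in the mean (6, highest other 0). These draws also moved the narrow arrays between groups. They therefore cannot separate the labels from the place of those arrays, and chance is not excluded. Within a time, 3 arrays against 3 make 10 splits, too few for a share under 0.05. The real split gave 6 genes at ZT1, 51 at ZT7, 49 at ZT13 and 6571 at ZT19, and the highest other gave 0 at each.

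Without the 4 narrow arrays, 1 of 100 draws, the real one, gave as many genes for the average effect (6715, highest other 2140). The same held for the rhythm in controls (2559, highest other 919). So it was for the rhythm in sleep-restricted mice (2566, highest other 74) and in the mean (848, highest other 78). For the difference in rhythm 2 of 100 did, the real one with 3455 and another with 5052. The real count is thus not the highest of the draws, and why another draw gave more was not tested. Control mice at ZT19 have 1 array in these draws, so their spread is assumed, and chance is not excluded. The 10 splits at ZT7 (3191, highest other 0) are again too few for a share under 0.05.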

How the results depend on the processing

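The tests of the 4 narrow arrays and of the decimals in this part were chosen after the results were seen, and the other alternatives were planned. For each value below that moved, the cause was not tested, except that fewer genes or arrays enter by construction where the filter, threshold or set of arrays changed. With decimals as deposited or shifted cells blank, and with trend and robust moderation, each count stayed within 1.5 times.

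Without a filter, the effect of sleep restriction at ZT1 gave 19 genes, the effect of sleep restriction at ZT13 15 and the effect of sleep restriction at ZT19 9902. The 24-h rhythm in control mice gave 8, the 24-h rhythm, mean of both conditions, 2 and the gene list tests 54. With the filter at the 60th percentile, the average effect of sleep restriction gave 138, ZT1 2, the effect of sleep restriction at ZT7 18 and ZT13 20. The rhythm in controls gave 3, the 24-h rhythm in sleep-restricted mice 1, the mean 0 (limma, 314 at an unadjusted p under 0.05) and the difference in 24-h rhythm 5. With all named probe sets, the rhythm in TSR gave 16 and in the mean 10. With quantile normalization, the average effect gave 1590, ZT1 19, ZT7 129, ZT13 628, the rhythm in controls 86 and in the mean 20. Centring arrays on their medians gave 118 at ZT13. Without the trend, ZT1 gave 3 and the mean rhythm 2. At an adjusted p under 0.10, the average effect gave 569, ZT7 77, ZT13 159 and the rhythm in controls 31.

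Array weights gave 9259 for the average effect of sleep restriction, 3102 for the effect of sleep restriction at ZT1, 3949 for the effect of sleep restriction at ZT7, 6079 for the effect of sleep restriction at ZT13 and 9905 for the effect of sleep restriction at ZT19. They gave 10243 for the 24-h rhythm in control mice, 5128 for the 24-h rhythm in sleep-restricted mice, 9389 for the 24-h rhythm, mean of both conditions, and 10281 for the difference in 24-h rhythm. In CON ZT19 the weight was 0.018 for the typical replicate 1, and 0.478 and 0.547 for the narrow replicates 2 and 3. The weighted mean of that group therefore rests on narrow arrays. The narrow arrays as a block gave, in the same order, 5825, 219, 1752, 3707, 2011, 1027, 576, 337 and 1421. Without the 4 narrow arrays the counts were 6715, 1200, 3191, 5483, 2954, 2559, 2566, 848 and 3455, and with quantile normalization as well 7020, 1492, 3837, 5917, 3328, 3303, 3257, 1419 and 4064. With the replicate block and without the narrow arrays they were 6601, 1052, 3123, 5533, 2286, 2506, 2391, 799 and 3114. The replicate block with all 24 arrays gave 27 at ZT13 and moved no other count over 1.5 times. The replicate numbers share only a number: the median correlation of deviations over 84 same-numbered pairs was -0.006, against 0.005 in other pairs.

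Only the 6 arrays of a time gave 0 for the effect of sleep restriction at ZT1 (limma, 144 at an unadjusted p under 0.05), 2101 for the effect of sleep restriction at ZT7, 0 for the effect of sleep restriction at ZT13 (1031) and 4 for the effect of sleep restriction at ZT19. The additive model gave 126 for the average effect of sleep restriction. Only the 12 arrays of a condition gave 46 for the 24-h rhythm in control mice and 1 for the 24-h rhythm in sleep-restricted mice. With 3 df of time, controls gave 34 and the 24-h rhythm, mean of both conditions, 16. The cosinor gave 3 in sleep-restricted mice, 1 in the mean and 10 for the difference in 24-h rhythm. The gene list tests gave 0 with estimated correlation (camera, 11 at an unadjusted p under 0.05), and 4 without the narrow arrays with it.

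The amplitude ratio in genes rhythmic on average, -0.41, was -2.57 in the core clock list, 0.03 without the 4 narrow arrays and -1.25 in the core clock list without them. The peak time shift in genes rhythmic on average, 3.61 h, was -10.61 h in the core clock list and -10.78 h in that list without the narrow arrays. In the genes rhythmic on average it was 0.63 h without the narrow arrays, 0.54 h with quantile normalization, 1.16 h without a filter and 4.33 h with the replicate block.

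Leaving out 1 array at a time gave ranges. The average effect of sleep restriction ran from 155 (without TSR ZT19 replicate 1) to 1291 (without TSR ZT13 replicate 2). The effect of sleep restriction at ZT1 ran from 1 (TSR ZT1 replicate 2) to 9 (TSR ZT13 replicate 2), at ZT7 from 2 (CON ZT7 replicate 1) to 114 (TSR ZT1 replicate 3), at ZT13 from 7 (CON ZT13 replicate 3) to 415 (TSR ZT1 replicate 3) and at ZT19 from 1 (TSR ZT19 replicate 2) to 9275 (CON ZT19 replicate 1). The 24-h rhythm in control mice ran from 6 (CON ZT7 replicate 1) to 7794 (CON ZT19 replicate 1), in sleep-restricted mice from 3 (TSR ZT19 replicate 3) to 38 (TSR ZT1 replicate 3), in the mean from 2 (TSR ZT1 replicate 2) to 78 (TSR ZT1 replicate 3), and the difference in 24-h rhythm from 7 (CON ZT7 replicate 2) to 3440 (CON ZT19 replicate 1). The gene list tests ran from 16 (TSR ZT13 replicate 2) to 30 (TSR ZT1 replicate 3). The amplitude ratio in genes rhythmic on average ran from -1.63 (CON ZT19 replicate 1) to 0.18 (CON ZT7 replicate 1), and the peak time shift in genes rhythmic on average from -1.57 h (TSR ZT1 replicate 3) to 4.88 h (CON ZT7 replicate 1), with -0.54 h without CON ZT19 replicate 1.

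Of 252 values of named genes, 246 kept their side of the threshold without the trend, 243 without a filter, 200 with quantile normalization, 248 with the replicate block and 161 without the narrow arrays. In these 5 alternatives no value past the threshold changed sign. With quantile normalization 27 newly passed, 17 no longer did, and 8 gave no value, since their genes fell under the filter. Without the narrow arrays 91 newly passed. Genes under the filter, Agrp, Pomc and Fos among them, were not shown to stand above the background of the arrays, so signal limits what can be seen of them.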

Other observations

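The lists tested in this part, except that of oligodendrocytes and myelin, were written after the ranked genes had been seen. Genes of motile cilia, which line the ventricle next to the mediobasal hypothalamus, had lower medians in TSR at ZT7 and ZT13 and a higher one at ZT19. Whether the members moved together was not tested. Of 17 tested members 6 fell at ZT7, with a median of -0.80 log2, and 3 fell at ZT13, with a median of -0.66. At ZT19 13 rose, with a median of 0.57, where the median over all genes was 0.60. The list lay at percentile 99.4 of random lists of like level there. Without the 4 narrow arrays 16 fell at ZT7 and 5 rose at ZT19, with a median of 0.20. Genes of cholinergic neurons went up at ZT7, where 6 of 8 rose, and 5 rose at ZT19, with a median of 0.80 (percentile 90.6 of random lists, where the median over all genes was 0.60). Without the narrow arrays 6 rose and 2 fell at ZT7, Zic4 with -0.47 and Ecel1 with -0.55. Cortical markers, of which 16 of 20 were tested, had medians of 0.12 at ZT7, 0.08 at ZT13 and -0.01 in the average. Striatal markers, 15 tested, had medians of 0.41 at ZT7, -0.43 at ZT13 and 0.74 at ZT19 (percentile 68.9 of random lists at ZT19). Without the narrow arrays the striatal medians were 0.41, -0.18 and 0.41. The cholinergic median at ZT19 was then 0.61, and the median over all genes 0.08. Both lists thus lay above the median gene at ZT19 there, where controls have 1 array. Of 20 listed, 15 passed the expression filter and 2 are in lists fixed earlier. Penk and Pde1b had the highest signals among them, although signals of different probe sets do not rank transcripts. At ZT7 Penk had 11.08 in controls and 11.49 in sleep-restricted mice, and Pde1b 8.57 and 8.97.

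Liver plasma protein genes, 8 of them tested, were higher at ZT1, with medians of 1.14 with 24 arrays and 1.42 with 20. The 4 that rose with 24 arrays were Serpina1c, Alb, Apoa1 and Ttr, the genes named at ZT1. This list was written after they had been seen, and they were not taken out of it. The count of 4 therefore repeats them and adds no separate evidence. At ZT7 the median was -0.68 with 24 arrays, and 7 fell with 20. At ZT19 4 rose in either set of arrays, with medians of 0.82 and 0.93. Of 110 small noncoding RNAs 4 fell in the average effect with 24 arrays, while 29 fell and 23 rose with 20, with a median of -0.04 in both. In the mean of the 2 conditions, 16 of 18 oligodendrocyte and myelin markers were rhythmic with 20 arrays (Fisher's exact test, adjusted p = 1.61e-15), against 7.02% of other genes. With all 24 arrays 0 of 18 passed over all genes in limma, 12 adjusted over the list alone (adjusted p = 1). Mag peaked at ZT 5.9 and Mbp at ZT 4.3. The control part of the result with 20 arrays rests on 1 array at ZT19. There the mean of the myelin markers was -0.520 log2 units, against -0.178 to 0.078 in the other typical control arrays.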
